A study of Arabidopsis thaliana with 12 samples.

How the data were processed

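RNA of 6 samples of wounded and 6 of untreated plants was measured, 1 array per sample, and the groups and replicate numbers were taken from the titles of the samples. The authors deposited a table of intensity values on a linear scale, with no value below 0, for 3439 probes. The array type, the background correction and the scaling behind these values are not given in the sources used here. The mean intensity per array lay between 0.983 and 1.09. On 5 arrays the largest values stopped just under 100 (1 to 4 values per array), and wounded replicate 4 alone had values over 100, 2 in number, up to 193. The table gave no signal over background, so the precision rests on the number of arrays alone.

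Gene names came from a platform annotation that can be old. Names were updated through gene identifiers to the RefSeq gene table of the TAIR10.1 assembly, where 690 of the 692 single-gene probes matched 689 loci and 2 kept the annotation's name. Probes naming several genes were tested but given no gene name, and probes without a listed gene are unnamed here. No genome build is named for the table, so no coordinates are given.

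Values of exactly 0 were treated as missing and the others were put on the log2 scale. The medians of the arrays spread over 0.825 on that scale, above the limit of 0.1 fixed before the data were examined, so the arrays were quantile-normalized with limma. A probe was tested when at least 4 arrays of each group had a value, which left 3233 probes over 12 arrays. The comparison used lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are wounded over untreated on the quantile-normalized scale. Errors beside log2 differences are moderated standard errors.

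Because wounded replicate 4 stood apart, every result was computed a second time without it, over 11 arrays and 3203 probes; this was decided after seeing the data. The arrays that looked alike were also fitted as a random block and averaged, likewise after seeing the data.

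The genes named are, among probes naming 1 gene, up to 12 with the largest rise and up to 12 with the largest fall past the threshold. As fewer than 10 passed over the 12 arrays, the 10 with the smallest p are named too, and from each list up to 4 measured members with the smallest p. A set of wound, defence, photosynthesis and actin genes was to be named whenever measured, and 0 of them had a single-gene probe. The rule was fixed before the data were examined; its use on the 11 arrays was not.

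Gene lists were tested with camera, with a preset correlation of 0.01, where at least 4 members were measured; a gene was represented by its brightest probe. The estimated correlation and fry were alternatives. As camera takes no missing values, lists were tested on 3034 probes measured on all 12 arrays and on 3087 over the 11. A planned list of cytosolic ribosomal proteins was left out because the reference used here held no gene descriptions. The 10 added lists were light reactions and their assembly, plastid carbon metabolism, pigment synthesis and fibrillins, plastid ribosomal proteins, organelle RNA factors, stress and defence genes, antioxidant enzymes, fatty acid synthesis, amino acid, nucleotide and cofactor synthesis, and histone H3 and mitosis.

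Alternatives covered the replicate number as a block, the scaling between arrays, filters on dim or incomplete probes, offsets of 50 and 0.1 before log2, an intensity trend, array weights, other thresholds, averaging of probes and leaving out each array or number in turn. The fit was tested on simulated data made with the means and spreads of the real probes, with 200 changed probes and independent arrays. In all simulations the errors were drawn independently for each probe. In the comparison of wounded with untreated over 12 arrays and 3233 probes, 22.4% of 67 probes changed 1.5-fold, 35.8% of 67 changed 2-fold and 72.7% of 66 changed 3-fold were recovered. There the spread included wounded replicate 4 and was drawn equally for every array, unlike in the real data. These shares therefore need not hold for the real fit over 12 arrays. Over 11 arrays and 3203 probes the shares were 40.3%, 76.1% and 87.9%. With a correlation of 0.8 within the alike arrays, added after seeing the data, a median of 125.5 unchanged probes were called over 11 arrays and 87.5 over 12 in 20 simulations, against 10 and 9 with independent arrays, so a share recovered says nothing of how many calls are false. In the real data the estimated correlation was 0.801 over 11 arrays and 0.937 over 12. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.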

Results

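Messenger RNA levels were measured with arrays in Arabidopsis thaliana plants of the Columbia accession, the common laboratory wild type. One group of plants had been wounded mechanically by cuts into the leaves and was taken 2 days later, and the other group was left untreated. The labels gave no day of harvest for the untreated plants, so a difference in harvest time cannot be told apart from wounding. Each group held 6 arrays. The table listed 3439 probes, of which 692 named 1 gene, 870 named several genes and 1877 had no gene listed. Mean intensities per array lay between 0.983 and 1.09, and between 4.77% and 5.90% of the values of an array were exactly 0. The labels did not say whether the arrays of a group came from separate plants or separate extracts, so the p-values measure only the spread between these arrays, which may be technical. The small number of arrays limits the precision.

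The 11 arrays other than wounded replicate 4 correlated with each other at r between 0.876 and 0.985 over probes. Wounded replicate 4 correlated with them at r between 0.430 and 0.500. A set of 5 pairs of arrays were closer to each other than to any further array of their group, with r between 0.953 and 0.985. These pairs were untreated 1 and 2, untreated 3 and 4, untreated 5 and 6, wounded 2 and 3, and wounded 5 and 6. Other pairs lay between 0.926 and 0.944 within the untreated group, between 0.876 and 0.936 within the wounded group without replicate 4, and between 0.885 and 0.946 across the groups. Wounded 5 and 6 correlated with untreated 1 and 2 at r between 0.936 and 0.946, and with wounded 1 to 3 at r between 0.876 and 0.889.

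**Figure D1:**
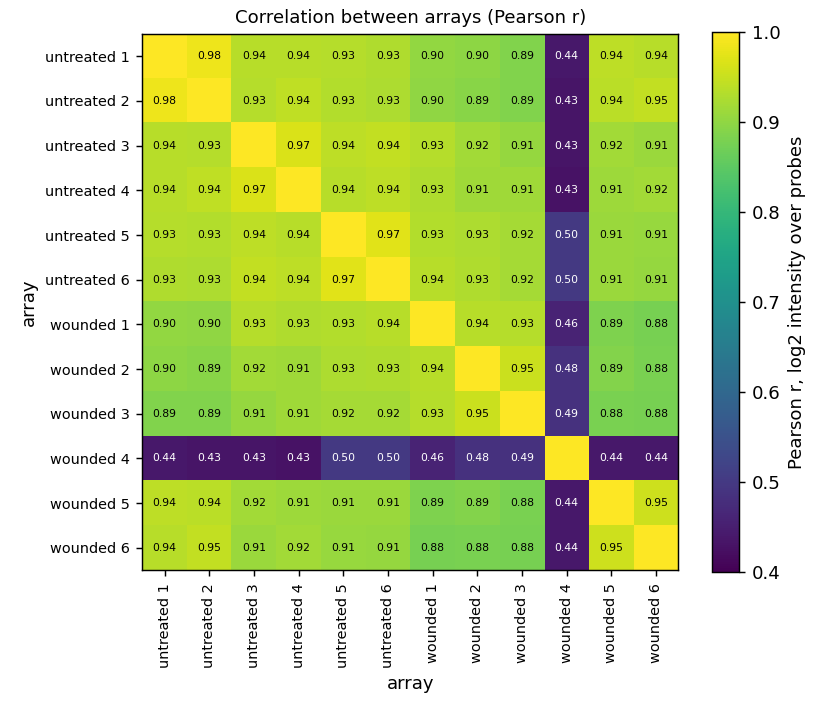
Pearson correlation of quantile-normalized log2 intensity over probes for each pair of the 12 arrays, with array names on both axes and the colour scale running over r. Wounded replicate 4 lies between 0.430 and 0.500 with all other arrays, and the 5 closest pairs lie between 0.953 and 0.985.

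The comparison of wounded with untreated plants asked which transcripts differed 2 days after leaf cutting. Over all 12 arrays, AT4G02040 had a mean log2 difference of -0.97 ± 0.22 (SE, n = 6 and 6, limma adjusted p = 0.193), and AT5G55570 one of -1.27 ± 0.28 (adjusted p = 0.193). LPA19, an assembly factor of photosystem II, had a log2 difference of -0.68 ± 0.17 and an adjusted p of 0.200. AT1G54500, a rubredoxin of the chloroplast, had one of -0.87 ± 0.23, and AT2G04540, a mitochondrial ketoacyl-ACP synthase of fatty acid synthesis, one of -0.86 ± 0.22, both with an adjusted p of 0.216. The pentatricopeptide repeat gene AT2G17670 had a log2 difference of 1.37 ± 0.36 and the sugar transporter family gene AT5G59250 one of 0.95 ± 0.25, also both at an adjusted p of 0.216. AT4G16060 had one of 1.01 ± 0.22 (adjusted p = 0.200), while the MADS-box gene AGL54 had -0.95 ± 0.25 and the pentatricopeptide repeat gene AT5G15280 had -0.92 ± 0.25, both with an adjusted p of 0.229. These 10 genes had the smallest p-values among probes naming 1 gene.

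With limma, 0 of the 3233 probes tested over the 12 arrays passed the threshold, and 376 had an unadjusted p under 0.05. The largest effect of a single array was that of wounded replicate 4, without which 71 of 3203 probes passed, 31 higher and 40 lower in wounded plants. With the values as deposited, without further scaling between arrays, 0 probes were higher and 7 lower over the 12 arrays, with a median log2 change of -0.32 over all probes in place of -0.02.

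In a second run of all results, wounded replicate 4 was left out after the scaling, by a choice made once the arrays were compared. Without it, 9 genes named by a single-gene probe rose and 13 fell. This fit counted the alike arrays as separate samples. With them as a random block, the lowest adjusted p in limma was 0.390 among the rises named here and 0.149 among the falls. XERICO, a RING zinc finger gene known from abscisic acid signalling, rose 1.70-fold (log2 0.77 ± 0.14 SE, n = 5 and 6, limma adjusted p = 0.0266). AT2G17670 rose 2.07-fold (log2 1.05 ± 0.22) and AT5G59250 rose 1.69-fold (log2 0.76 ± 0.16), both with an adjusted p of 0.0398. AT4G16060 rose 1.91-fold (log2 0.93 ± 0.19, adjusted p = 0.0419), with values in only 4 of the untreated arrays because the other 2 were listed at 0. AT2G17670 and AT4G16060 were dim, at mean log2 intensities of -2.72 and -3.05 in the wounded arrays and -3.77 and -3.98 in the untreated ones. The medians of the arrays before scaling lay between -1.59 and -0.77. AT3G57440 rose 1.72-fold, AT5G66050 1.65-fold and AT4G09620 by 0.67 on the log2 scale, although wounded replicate 4 lay below the untreated mean for all of these. The exostosin family gene AT3G57630 rose 1.44-fold and AT4G29890, which resembles choline monooxygenase, rose 1.43-fold, again with wounded replicate 4 below the untreated mean.

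Among the genes that fell without wounded replicate 4, AT4G02040 had the smallest adjusted p, at 0.00722, with a log2 change of -0.77 ± 0.10 (SE). SWAP70, a guanine nucleotide exchange factor, had the largest fall, to 0.414-fold (log2 -1.27 ± 0.28, adjusted p = 0.0419), with wounded replicate 4 above the untreated mean, and AT5G55570 fell to 0.447-fold. SWAP70 was dim too, at a mean log2 intensity of -3.60 in the wounded and -2.32 in the untreated arrays. AGL54 fell to 0.598-fold, AT4G05070 to 0.603-fold and AT2G28755 to 0.632-fold. The rubredoxin gene AT1G54500 fell to 0.628-fold (adjusted p = 0.0266) and LPA19 to 0.641-fold (adjusted p = 0.0478). AT2G04540 fell to 0.634-fold (adjusted p = 0.0253). The AP2/ERF family gene AT4G31060 fell to 0.680-fold, the RNA-binding protein gene UBA1A to 0.691-fold and the lipid transfer family gene AT4G22490 to 0.692-fold.

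None of these 71 probes passed over all probes when the alike arrays were fitted as a random block, where limma found 0 probes, 243 with an unadjusted p under 0.05 and a smallest adjusted p of 0.149, for AT4G02040. Leaving out 1 further array gave between 2 probes (without untreated 4) and 125 (without wounded 1). Counting each named gene in each fit without a further array or number, the 21 genes still passed in 66 cases and no longer in 283. The split of 31 higher and 40 lower depended on the scaling, with 48 higher and 24 lower after median centring, and 6 higher and 81 lower with the values as deposited, where the median log2 change of all probes was -0.31 in place of -0.02.

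**Figure D2:**
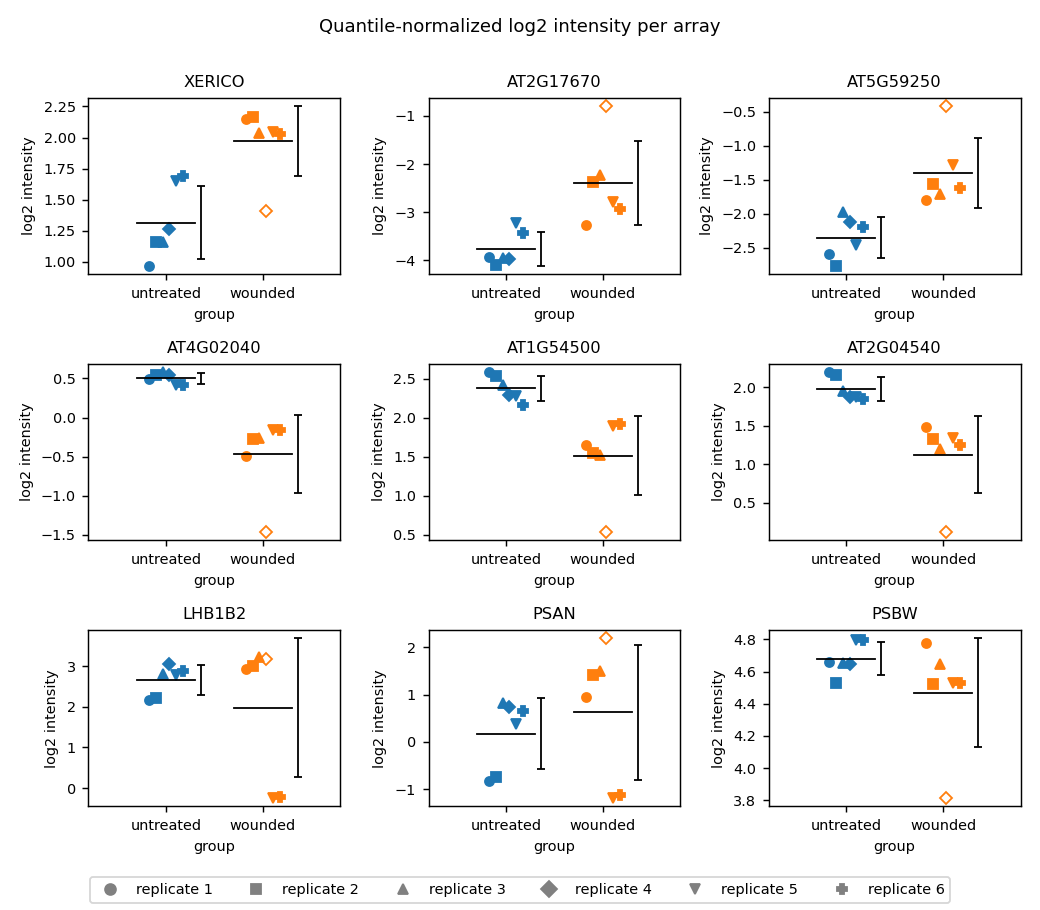
Quantile-normalized log2 intensity (vertical axis) of 9 genes in the 6 untreated and 6 wounded arrays, 1 marker shape per replicate number, with the group mean as a line and the SD over the 6 arrays as an error bar beside it. Wounded replicate 4, the open marker, lies apart from the other wounded arrays for most genes, and wounded 5 and 6 lie at -0.25 and -0.22 for LHB1B2 where wounded 1 to 3 lie between 2.92 and 3.22.

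Of the 430 genes in the 30 lists fixed beforehand, 7 had a single-gene probe. Neither jasmonate list nor any other list of wound-response, defence, hormone or stress genes had a member with a single-gene probe, and the same held for the lists of cell type markers and of housekeeping genes. Probes naming several genes or none may still cover them. Of photosystem and light-harvesting genes, 4 had a single-gene probe and none passed the threshold over 12 or 11 arrays. PSBY, a photosystem II subunit, had a log2 difference of 0.63 ± 0.32 (SE) over the 12 arrays, and PSBW, another one, -0.21 ± 0.17. LHB1B2, a chlorophyll a/b-binding protein of light-harvesting complex II, had -0.68 ± 0.64, and PSAN, a photosystem I subunit, 0.45 ± 0.60. Without wounded replicate 4 these became 0.36 ± 0.22 for PSBY, -0.078 ± 0.097 for PSBW, -0.92 ± 0.66 for LHB1B2 and 0.14 ± 0.57 for PSAN. The list had a camera p of 0.796 (adjusted p = 0.842 with an estimated correlation, and adjusted p = 0.0196 with the values as deposited and the preset correlation), its median log2 change was 0.12, and 0 members passed adjusted over the list alone. The Calvin cycle genes PRK (phosphoribulokinase, 0.41 ± 0.27) and SBPASE (sedoheptulose bisphosphatase, 0.11 ± 0.25) and the chlorophyll synthesis gene CHLM (0.20 ± 0.40) did not pass either, with 0 calls adjusted over the list alone, and without wounded replicate 4 they had 0.15 ± 0.10, 0.014 ± 0.23 and -0.081 ± 0.33. The sign of PSBW, SBPASE and CHLM turned with the values as deposited, where the median log2 change of all probes was lower, as given above. SBPASE and CHLM moved in the direction of that shift and PSBW against it.

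A further 10 lists were assembled from the genes that the probes named, before any test was run. None of the 9 with at least 4 measured members passed in camera, where the adjusted p was 0.946 over 12 arrays and 0.983 over 11 arrays for each of them (adjusted p between 0.961 and 0.969 over 12 arrays, and 0.983 over 11, with an estimated correlation). Over the 11 arrays, fry's test for change in either direction had an adjusted p of 0.00282 for light reactions, 0.00343 for organelle RNA factors and 0.00282 for stress genes, but over all 12 arrays it was 0.523, 0.523 and 0.653, and its test for movement one way had none under 0.0892 over the 11 arrays. Both tests of fry ask whether list members changed at all, not whether they changed more than other probes. Over the 11 arrays, 667 of all 3203 probes (20.8%) had an unadjusted p under 0.05 in limma. The list tests of camera and fry took the alike arrays as separate samples, which can make p too small. No list test was run with the alike arrays as a block. Among 13 genes of the light reactions and their assembly, LPA19 and AT1G54500 fell without wounded replicate 4 and 11 did not pass. As above, no such call over all probes held with the alike arrays as a random block. AT1G22700, known as PYG7, had a log2 difference of -0.23 ± 0.24 (SE) over the 11 arrays. Of 24 organelle RNA factors, AT2G17670 rose and 23 did not pass, among them AT5G39980 at 0.84 ± 0.34, AT5G15280 at -0.77 ± 0.21 and AT2G46050 at -0.26 ± 0.13. Of 9 stress-inducible and defence genes tested over the 11 arrays, XERICO rose and 8 did not pass, among them SIS at -0.38 ± 0.10, MAMI at 0.21 ± 0.17 and AT4G39230 at 2.84 ± 1.24, which became 1.64 ± 0.48 without untreated replicate 4, listed near 0. Of 3 fatty acid synthesis genes, AT2G04540 fell, while FATB, an acyl-ACP thioesterase, had 0.45 ± 0.12 and AT1G24360 had -0.25 ± 0.12.

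Adjusted over its list alone, 6 members of the added lists passed over the 12 arrays, namely AT1G54500 and LPA19 (adjusted p = 0.0141 for both), AT2G17670 and AT5G15280 (0.0356 for both), XERICO (0.0427) and AT2G04540 (0.00634). This adjustment did not span the 10 added lists, and none of these 6 passed adjusted over all probes. AT2G04540 was 1 of only 3 genes tested in its list. The count became 3 without untreated 1, 2 or 3 or wounded 2, 3 or 5, each left out alone, and 9 without wounded replicate 4. Those 9 were the same 6 genes with SIS (0.0124), CCS (0.0154) and FATB (0.00573). With the alike arrays as a random block, AT2G04540 passed over the 12 arrays (0.0381), and AT2G04540 (0.00294), XERICO (0.0109) and AT1G54500 (0.0128) passed over the 11, and 0 and 1 members passed with the alike arrays averaged.

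In the other added lists no member passed over 11 arrays when adjusted over all probes, and the values of AT1G64510, SRX and AT1G13370 had the opposite sign over all 12 arrays (-0.05, 0.40 and 0.60). For 7 genes of plastid carbon metabolism and its redox control, AT5G58330 had a log2 difference of -0.26 ± 0.12 (SE), NTRC 0.30 ± 0.25, AT2G04700 0.14 ± 0.15 and PRK 0.15 ± 0.10. For 9 genes of pigment synthesis and fibrillins, SIRB (sirohydrochlorin ferrochelatase) had -0.34 ± 0.12, AT1G74470 -0.23 ± 0.11, AT2G35490 0.17 ± 0.19 and HEMA3 0.04 ± 0.15. For 5 plastid ribosomal protein genes, AT1G64510 had 0.40 ± 0.14, AT1G29070 -0.37 ± 0.19, AT4G01310 0.33 ± 0.21 and AT3G54210 0.07 ± 0.13. For 5 antioxidant and detoxification genes, CCS, the copper chaperone of superoxide dismutase, had -0.34 ± 0.09, GLX2-1 0.55 ± 0.28, SRX (sulfiredoxin) -0.36 ± 0.31 and GLDH 0.06 ± 0.13. For 9 genes of amino acid, nucleotide and cofactor synthesis, AT1G31220 had -0.61 ± 0.19, AT3G58610 -0.39 ± 0.13, AT2G35390 0.62 ± 0.22 and AT-HF 0.33 ± 0.28. For 5 genes of histone H3 and mitosis, AT3G44050 had -0.05 ± 0.12, AT1G13370 -0.27 ± 0.21, AT1G09200 0.14 ± 0.24 and AT2G37420 0.04 ± 0.17.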

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

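The tests on wounded replicate 4, on single arrays far from the rest over all probes, on splits of the 11 arrays and on the alike arrays were chosen after the results were seen; the removal of a trend along the probe numbers and the splits of the 12 arrays were planned before their results. The correlation of neighbouring probe numbers had been seen before the trend removal was planned, and the shuffled orders set beside it were added after its count of 18 had been seen.

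Wounded replicate 4 stood apart from the other arrays of its group. Its median correlation with the other arrays was 0.44, against 0.906 for the nearest other wounded array, a gap of 0.954 of the group's range. Of 3068 probes with values on all 6 wounded arrays, 37.0% had a single array far from the other 5, where chance gives about 1 in 20, and it was wounded replicate 4 for 1094 of these 1136 probes, lowest for 708 and highest for 386; among the untreated arrays the share was 3.53% of 3175 probes. Of the 60 named genes, 30 were so placed, all by wounded replicate 4, lowest for 23 and highest for 7, but many of them were named because they passed without it, so the chance rate does not apply to them. Its gap, as a share of the range, was 0.928 for AT1G24360, 0.899 for CCS, 0.890 for AT4G22490, 0.884 for AT1G22700, 0.865 for AT3G44050, 0.856 for AT5G58330, 0.853 for SIRB and 0.849 for AT1G13370. It was 0.842 for PRK, 0.840 for AT1G64510, 0.831 for SIS, 0.821 for XERICO, 0.817 for AT3G54210, 0.794 for AT2G04540, 0.784 for AT3G57440, 0.782 for AT3G58610, 0.778 for AT5G66050 and 0.777 for AT4G31060. It was 0.753 for AT2G28755, 0.753 for GLDH, 0.752 for HEMA3, 0.747 for AT4G02040, 0.735 for PSBW, 0.724 for AT4G09620, 0.717 for AT1G54500 and 0.698 for PSBY. It was 0.691 for AT4G29890, 0.673 for AT4G05070, 0.643 for FATB and 0.633 for AT5G59250. Among the untreated arrays, AT4G39230 was the only named gene so placed, with untreated replicate 4 at -12.29 on the log2 scale and a gap of 0.753 over 5 measured arrays.

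A uniform shift of the rows in the column of wounded replicate 4 would bring back a high correlation at some other probe number, and the highest found within 300 numbers was 0.142. A step that keeps the order of the values would leave its rank correlation as high as that of the other arrays, at 0.915 or more, and the highest was 0.506. An untreated array under a wrong label would resemble the untreated arrays, and its highest correlation with one of them was 0.500, against 0.876 as the lowest among the other 11 arrays. An irregular reordering of rows, a failed hybridization and RNA from other material were not tested. No biological explanation was tested, since the labels give this array the treatment of its group.

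Over the 12 arrays, 100 of 100 splits into 6 and 6 gave at least the real count of 0 probes, as any split must, so this count says nothing about chance; the highest other split gave 60. Without wounded replicate 4, 2 of 100 splits into 5 and 6 gave at least 71 probes, the real one among them. Such splits can part the alike arrays, and with them kept together only 10 splits exist, too few for a share under 0.05, with 558 as the highest other against 71. The split with 558 probes had wounded 1 to 3 and untreated 5 and 6 on one side. A structure of the samples may lie behind it, but this was not tested.

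The 71 probes past the threshold without wounded replicate 4 were set against 2 technical explanations. Of the 10 splits that keep the alike arrays together, 3 gave at least as many probes, with 558 and 82 for the others and 71 for the real one, so arrays that share a source may have been counted as separate samples. In simulated data without any change and a correlation of 0.8 within alike arrays, the same fit called a median of 35 probes, and up to 78. The simulated probes varied independently of each other, so this range need not hold where probes vary together. After a running median along the probe numbers was taken from each array, 18 probes passed, 12 of them among the 71. In 20 shuffled orders the same removal left 37 to 78. A trend along the probe numbers may thus account for part of the count. Whether these numbers follow positions on the array is not given in the sources used here. The removal therefore cannot tell a position effect from other changes shared by neighbouring numbers. It was also incomplete, as neighbouring log2 changes still correlated at r = 0.0915. The highest r was 0.0702 in 1000 shuffles of the changes before removal. Differences within the alike pairs gave r between -0.0583 and 0.0411, so such a trend would have to be largely shared by alike arrays. The median size of the 71 log2 changes went from 0.67 to 0.56 with a standard error of 0.13 before and after. An effect of wounding stays open beside both.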

How the results depend on the processing

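Leaving out each array in turn was planned; using the 11 arrays without wounded replicate 4 as a second base, the alike-array fits, the offset of 0.1 and the sets without wounded 1 to 3 or 5 and 6 were chosen after seeing the data, and the cause of the differences below was not tested. Over 12 arrays the count of 0 probes became 7 with the values as deposited, 19 with an offset of 50, 1 with an offset of 0.1 and 179 with array weights, which can weigh single arrays down. The offset of 50 was far above the mean intensities per array of 0.983 to 1.09, so it strongly compressed the log2 changes. Leaving out arrays or numbers gave 0 to 71; 2 passed without replicate 4 of both groups. The replicate block gave 0 probes (256 at an unadjusted p under 0.05). Same-numbered arrays did not deviate together (r between -0.34 and 0.09), although all 5 alike pairs had consecutive numbers.

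Without wounded replicate 4 the count of 71 became 0 with the replicate block and 3 with random replicate blocks. It became 0 with alike arrays as a random block and 0 with them averaged. It was 123 with an offset of 50, 137 with an offset of 0.1 and 119 with array weights. It was 211 at an adjusted p below 0.1, 2 below 0.01 and 13 with at least 2-fold. It was 408 with wounded 5 and 6 left out too and 187 with wounded 1, 2 and 3 left out too. The latter set kept only the alike pair wounded 5 and 6 in its group. For both sets, and with alike arrays averaged, the smallest number of values required per group was lowered. Leaving out arrays or numbers gave 0 to 125: 4 without untreated 1, 3 without untreated 2, 5 without untreated 3, 2 without untreated 4, 50 without untreated 5, 29 without untreated 6, 125 without wounded 1, 3 without wounded 2, 6 without wounded 3, 30 without wounded 5 and 35 without wounded 6. Of the fixed lists, 1 passed in camera with the values as deposited over 12 and over 11 arrays (adjusted p = 0.0196 and 0.0409), and 0 otherwise. That call used the preset correlation and was not repeated with an estimated one. On the scaled values the estimate for this list was 0.218 over 12 and 0.633 over 11 arrays. No added list passed in camera or in fry's one-way test in any setting run.

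The counts of list members adjusted over their list alone were all varied after seeing the data. In the added lists over 12 arrays, 6 became 1 with the replicate block, 3 with random replicate blocks, 3 with median centring, 11 with array weights, 1 with alike arrays as a random block and 0 with them averaged, and 1 to 10 without single arrays or numbers. Over 11 arrays, 9 became 20 with the values as deposited, 5 with median centring, 3 with alike arrays as a random block and 1 with them averaged, and 5 to 11 without single arrays or numbers. In the fixed lists 0 passed over 12 and over 11 arrays, except 3 with wounded 1, 2 and 3 left out too, which kept only the alike pair wounded 5 and 6.

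Of the named genes' log2 changes over 12 arrays, all below the threshold, these changed sign. With the values as deposited they were PSBW (0.21), SBPASE (-0.23), CHLM (-0.14), AT2G04700 (-0.066), HEMA3 (-0.014), MAMI (-0.047), GLDH (-0.098), SRX (-0.11), AT1G09200 (-0.11) and AT2G37420 (-0.30). All of these but PSBW moved down, the direction in which the median of all probes shifted in that setting. With median centring PSBW (0.56) and AT1G64510 (0.028) did, with cyclic loess PSBW (0.083) and SRX (-0.067), and with array weights AT1G64510 (0.36), SRX (-0.13), AT1G13370 (-0.22) and AT2G37420 (-0.057). AT1G64510 did with offsets of 50 (0.00089) and 0.1 (0.058). With alike arrays as a random block AT5G66050 (-0.0052) and AT2G37420 (-0.014) did, and with them averaged AT5G66050 (-0.018) and AT2G37420 (-0.016). Without single arrays or numbers the range was -0.049 to 0.30 for SBPASE, -0.13 to 0.54 for CHLM, -0.014 to 0.48 for HEMA3, -0.20 to 0.41 for AT1G64510, -0.41 to 0.89 for SRX, -0.27 to 0.88 for AT1G13370 and -0.090 to 0.14 for AT2G37420.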

Other observations

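For LHB1B2, PSAN, CHLM and SBPASE, the wounded arrays differed among each other by more than the group means did. The same held for PSBW and PRK, with or without wounded replicate 4, so it sets none of these genes apart. It did not hold for AT1G54500 over the 11 arrays without wounded replicate 4. LHB1B2 lay between 2.92 and 3.22 on the log2 scale in wounded 1 to 4 and at -0.25 and -0.22 in wounded 5 and 6, while the untreated arrays lay between 2.17 and 3.06. PSAN lay at 0.94, 1.41, 1.49 and 2.19 in wounded 1 to 4 and at -1.19 and -1.12 in wounded 5 and 6, and at -0.83 and -0.74 in untreated 1 and 2 against 0.39 to 0.83 in untreated 3 to 6. CHLM lay between -1.98 and -0.40 in wounded 1 to 4 and at -2.72 and -2.99 in wounded 5 and 6. SBPASE lay at -1.03, -0.46, -0.30 and -0.40 in wounded 1 to 4 and at -1.50 and -1.46 in wounded 5 and 6. PSBW lay between 4.52 and 4.78 in the wounded arrays other than replicate 4, where it lay at 3.81. These genes were picked after their values were seen, and the differences among arrays were not tested.

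Over the 11 arrays, the first principal component held 35.7% of the variance and set untreated 1 and 2 and wounded 5 and 6, at 16.5, 16.5, 17.0 and 17.1, against wounded 1 to 3, at -15.1, -20.2 and -21.7. Untreated 3 to 6 lay between -5.77 and 1.09. The log2 changes of neighbouring probe numbers correlated at r = 0.179 over probes, above the highest value of 0.0702 in 1000 shuffled orders, and the differences within the 5 alike pairs gave r between -0.0583 and 0.0411. Of 3173 probes, 407 (12.8%) separated the groups fully once the alike arrays were averaged, where chance gives 10%.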
